A study of Homo sapiens with 6 samples.

How the data were processed

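RNA was measured in 6 libraries of HT-29 cells, 3 exposed to F. nucleatum and 3 given blank culture medium, grouped by the treatment named in the labels. Per the labels' protocols, the cells grew in RPMI-1640 with 10% serum at 37 °C and 5% CO2, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the tools were TopHat2 2.0.11, TopHat and HTSeq and the genome build was hg19 (GRCh37), while the role of each tool is not recorded in those notes. The annotation, the strand setting of the counting and any read filter are not given in the sources used here.

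Each deposited table holds raw read counts per gene name, not normalized, 1 table per library, with 56638 genes. It ends in 5 summary rows that name no gene. These stayed out of library sizes and tests. Of all reads in a table, 43.4% to 46.6% were counted as lying in no feature, 3.50% to 3.84% as ambiguous and 9.94% to 10.2% as aligned to more than 1 place. The share in no feature was 44.6%, 44.7% and 43.4% in F. nucleatum replicates 1 to 3 and 45.8%, 45.2% and 46.6% in control replicates 1 to 3. Counts assigned to genes ran from 15330313 to 18618711 per library, and 3 counts, the limit that a count of 0 allows, correspond to 0.161 to 0.196 CPM. Intervals and such limits cover counting error only. The 10 most abundant genes took 6.43% to 7.18% of the counts of a library.

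A count of reads shared between near-identical genes depends on how multiply aligned and ambiguous reads were set aside, so close paralogs, pseudogenes and histone or HLA genes are reported as uncertain. Because no strand setting is given, reads of a gene and of its antisense partner cannot be told apart. The genome annotation at hand (GENCODE v29) belongs to another build than the one in the notes, so no coordinates are given, and it served only for gene names and for the GC content and length of transcripts. Of the 20070 genes tested, 15619 (77.8%) had a name in the tables of current and older gene symbols.

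Libraries of a group were first compared with each other. The chi-square statistic of their counts over its degrees of freedom was 2.36 to 4.63 within groups and 6.50 to 10.3 between them, so no pair agreed within sampling noise and each library counts as 1 replicate. The labels give no sequencing batch or date.

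Differences between the groups were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts of all 6 libraries. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 20070 of 56638, and libraries were scaled by TMM. A quasi-likelihood model with the group as its only term was fitted (glmQLFit, glmQLFTest, without robust squeezing), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are F. nucleatum over control. The standard error given beside one is the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.0523. Per gene, CPM values were computed here from the deposited counts after TMM scaling.

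For gene groups, 36 lists with 950 entries, all 950 found in the tables, were written from general knowledge. Lists with at least 5 tested members were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 36 lists. Camera compares a list with all other genes. Each list was tested again with the correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way. The number of called members is given over all genes tested and adjusted over the list alone. One list holds 5 genes that the published study is thought to centre on, recalled from memory and not checked. The comparison, tests, lists, rule for named genes and most other settings were fixed before the data were examined.

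Genes were named by a rule: the 8 highest and the 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM, a gene symbol and all libraries of one group above all of the other, the 2 members of each list with the smallest p (4 where the list passed camera), and the 5 recalled genes of the published study. Other genes are named only where stated, and 3 genes that the rule picks are not reported here. The fit and the list test were tested on simulated counts for 19680 genes drawn from these libraries' means and sizes. Of genes changed 1.25-fold, 25.4% were recovered, of those changed 1.5-fold 61.2% and of those changed 2-fold 72.7%. At 5 CPM or more these shares were 39.5%, 90.5% and 97.6%. Of all calls at any level, 7.02% were false. The list test found the raised list, that of core autophagy genes, and called 1 list that had not been raised as a whole. Its name was not kept, and the list of recalled genes shares ULK1 and ATG7 with the raised list. Simulated genes were drawn independently, so the list test was not tried on correlated genes.

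Alternatives changed 1 choice at a time: other scalings, filters and tests (among them DESeq2 1.42.0 and limma-voom), the replicate number as a block, a fold threshold of 1.5, leaving out abundant genes, and leaving out each library in turn. Corrections for GC content and transcript length, and lists without shared members, were added after seeing the data. Only 79.3% of the tested genes could be matched to a transcript, so the total counts of called genes under these corrections are not used. All members of the lists were matched, and calls of list members and of lists under these corrections are given. All per-library columns of the deposited tables were used.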

Results

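The series measured RNA by sequencing in HT-29, an established human cell line grown from a colorectal adenocarcinoma. The cells had been exposed to Fusobacterium nucleatum, an anaerobic bacterium of the mouth that is also found in colorectal tumours, or to blank culture medium as the negative control. There were 6 libraries, 3 per group. The number of counts assigned to genes was 15330313, 18457238 and 15633744 in F. nucleatum replicates 1 to 3 and 18618711, 17041899 and 16278512 in control replicates 1 to 3, with 28474 to 29292 genes detected per library. The dose, the duration of exposure and the bacterial strain are not stated in the labels. Nothing in the labels says that the replicates of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Genes are named as in the deposited counts, and levels are given as CPM, the usual scaling of read counts to a common library size, after TMM normalization, as mean ± SD with n = 3 per group.

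The comparison of exposed with control cells asks which transcripts differ once HT-29 cells meet the bacterium. Among the gene lists, 27 of 30 tested members were higher with F. nucleatum in the amino acid response of ATF4, 19 of 29 in the interferon response and 19 of 31 in the immediate early class, while 23 of 31 were lower in mitosis and 15 of 24 in cholesterol synthesis. The camera calls of these 5 lists were lost with an estimated correlation between genes (adjusted p = 0.0576, 0.0517, 0.110, 0.0517 and 0.110 in that order). Of 20070 genes tested, 1497 were higher and 1066 lower with F. nucleatum by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Most differences were small: the median absolute log2 fold change of the called genes was 0.31, and 105 genes rose and 69 fell by at least 2-fold. The first principal component held 33.2% of the variance and separated the groups. Higher genes made up 58.4% of the calls with TMM, but 46.6% with upper-quartile normalization (1216 higher, 1394 lower) and 46.2% with library totals only (1210 higher, 1411 lower). The count of lower genes was 650 without F. nucleatum replicate 2, 688 without control replicate 1 and 1212 without F. nucleatum replicate 1. A test against a 1.5-fold change left 57 higher and 17 lower genes.

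**Figure D1:**
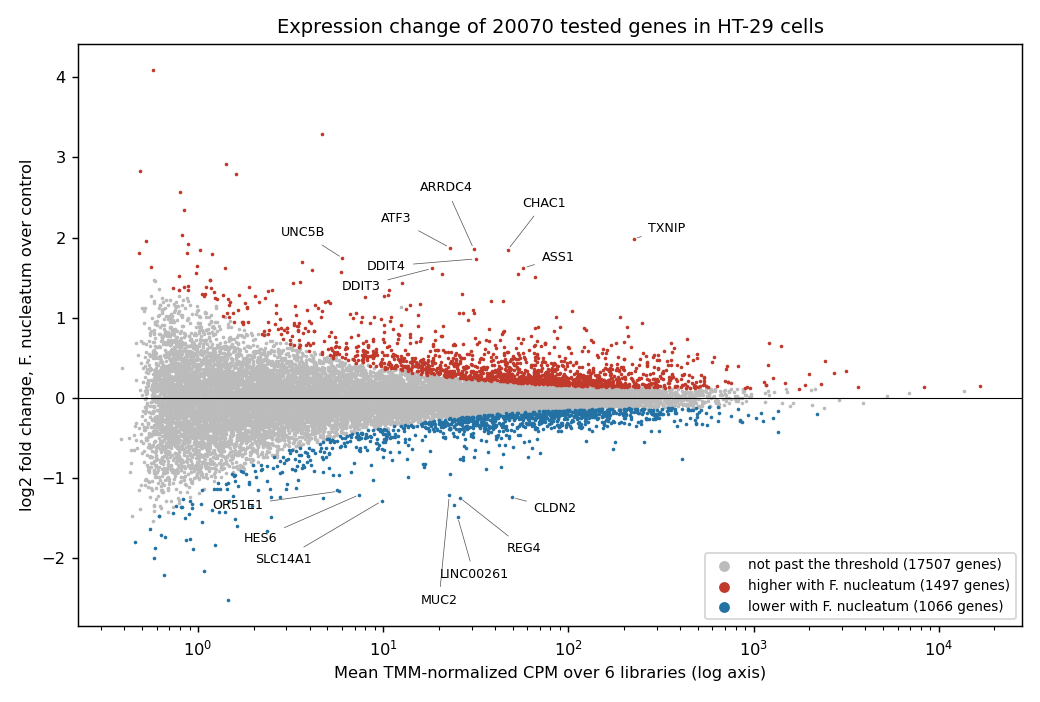
Each point is 1 of the 20070 tested genes, with its mean TMM-normalized CPM over the 6 libraries on the horizontal log axis and its log2 fold change, F. nucleatum over control, on the vertical axis. Red points are the 1497 genes higher and blue points the 1066 genes lower with F. nucleatum, and the 15 labelled genes run from 1.98 (TXNIP) to −1.49 (LINC00261).

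The most raised of the genes named by rule was TXNIP, which encodes an inhibitor of thioredoxin and of glucose uptake. It stood at 360.3 ± 78.7 CPM against 91.2 ± 5.05 CPM, a 3.95-fold difference (log2 fold change 1.98, SE 0.076, edgeR adjusted p = 6.52e-25). Its paralog ARRDC4 rose 3.62-fold, to 48.3 ± 8.58 CPM against 13.4 ± 0.429 CPM. The stress-induced transcription factors ATF3 and DDIT3 (CHOP) rose 3.66-fold and 3.06-fold, to 36 ± 9.09 and 27.6 ± 5.64 CPM. CHAC1, a glutathione-degrading enzyme, was at 73.6 ± 14.4 CPM against 20.5 ± 2.69 CPM. DDIT4, an inhibitor of mTORC1 signalling, was at 48.5 ± 12.2 CPM against 14.6 ± 2.40 CPM, and ASS1, the argininosuccinate synthetase of arginine synthesis, at 86.3 ± 17.8 CPM against 28.1 ± 1.41 CPM. UNC5B, a netrin receptor, completed these 8 genes with log2 fold change 1.74 at a lower level of 9.27 ± 2.49 CPM against 2.78 ± 0.646 CPM.

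At the other end, the long non-coding RNA LINC00261 was at 13.3 ± 1.54 CPM against 37.1 ± 0.435 CPM and fell by 1.49 on the log2 scale (SE 0.091, edgeR adjusted p = 1.28e-17). The goblet cell genes MUC2, the main gel-forming mucin of the colon, and REG4 were at 13.6 ± 0.891 CPM against 31.8 ± 1.10 CPM and 15.4 ± 1.76 CPM against 36.4 ± 0.409 CPM. CLDN2, which forms a cation pore in tight junctions, was at 29.5 ± 6.66 CPM against 69.7 ± 3.86 CPM. The urea transporter SLC14A1 (log2 fold change −1.29), the Notch-related transcription factor HES6 (−1.21) and the olfactory receptor OR51E1 (−1.17) fell as well, from 13.9, 10.4 and 7.93 CPM in control cells. For all 15 genes every library of one group lay above every library of the other, a separation that was part of the rule for naming them and that chance gives 10% of genes with 3 libraries against 3.

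**Figure D2:**
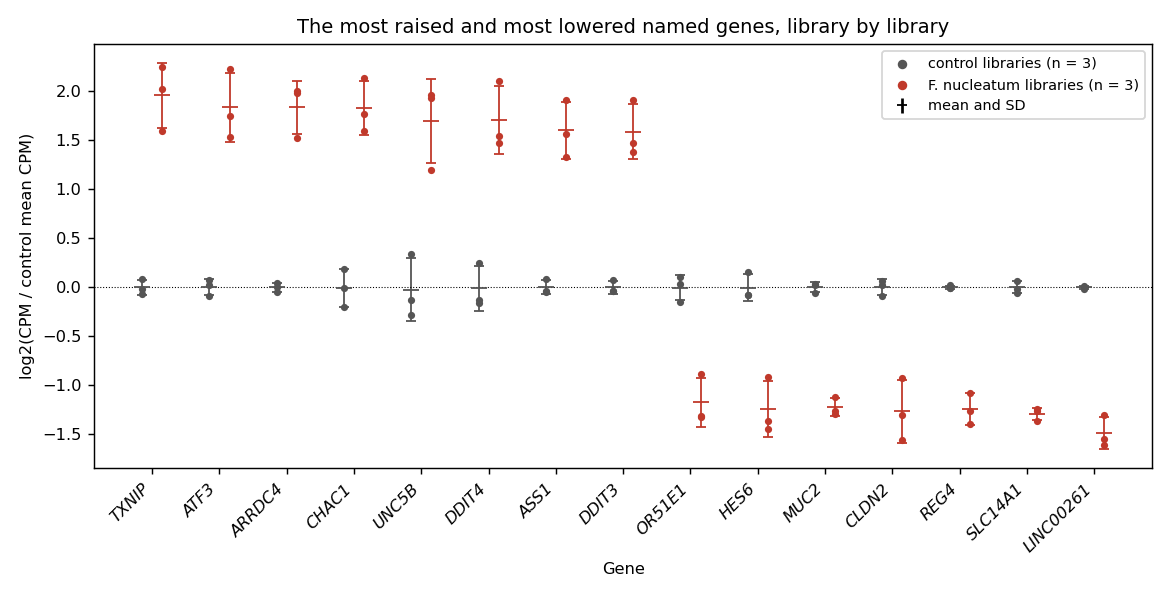
Points show the 3 libraries of each group as log2 of CPM over the mean CPM of the control libraries (vertical axis) for 15 of the most raised and most lowered named genes (horizontal axis), with mean and SD bars. The F. nucleatum libraries of TXNIP ranged from 276 to 433 CPM and its control libraries from 87 to 96.8 CPM.

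Of the 36 gene lists, 16 were higher and 9 lower with F. nucleatum at a camera adjusted p under 0.05 with the preset correlation of 0.01 between genes. Those 16 include the list of 5 genes recalled from the published study, which is no independent evidence. None of the 25 calls held with the correlation estimated from these libraries, where camera gave 0 lists past the threshold, 16 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0517, while fry put 20 lists past it, all but the lysosome list among the 25. Camera with the preset correlation also put 4 to 15 lists past the threshold in the 9 regroupings of the libraries that mix exposed and control cells, so the counts of single members are given beside each list. Those regroupings hold unequal numbers of exposed libraries on their sides, so part of the exposure difference remains in them. Lists that pass there need not be false calls.

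**Figure D3:**
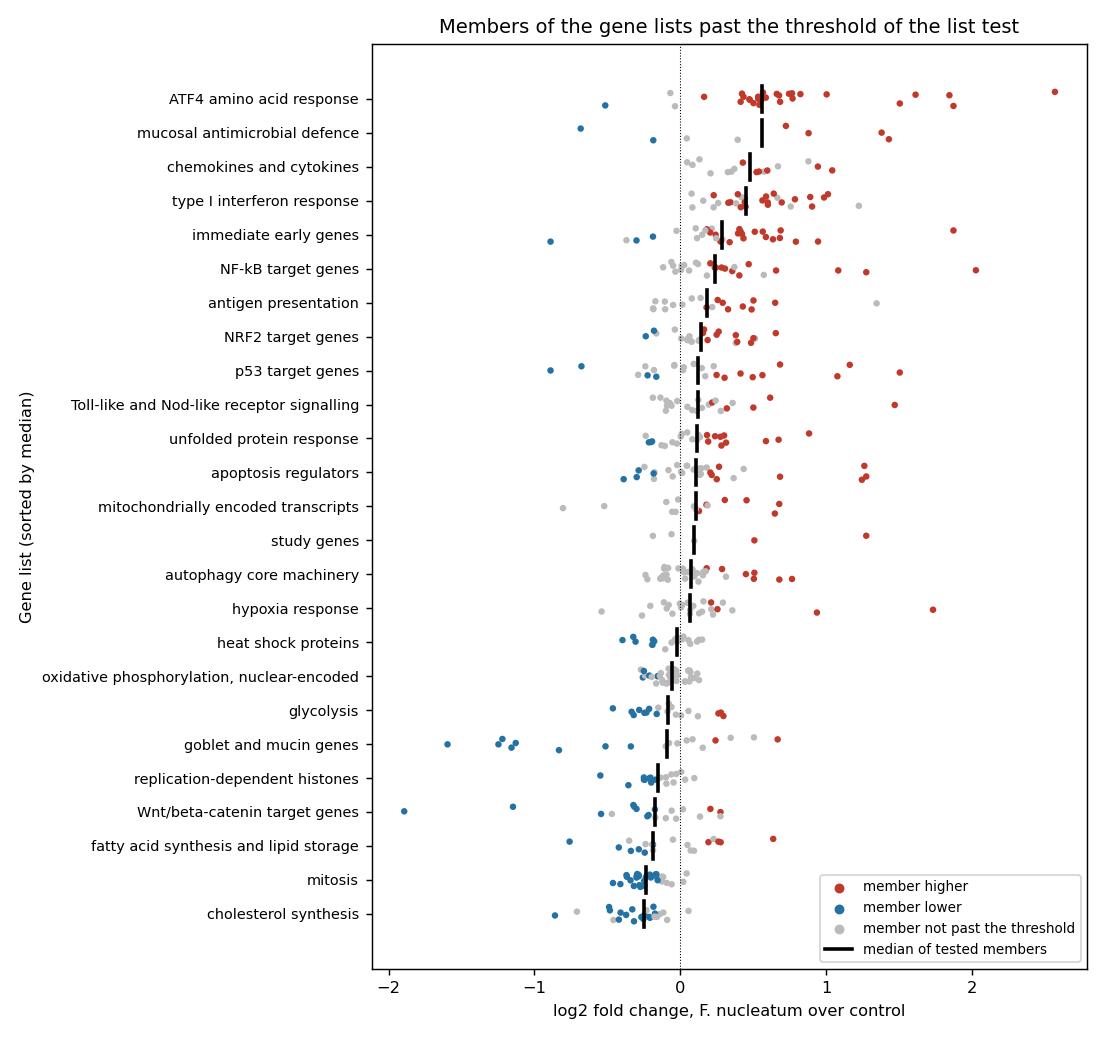
Each point is a tested member of a gene list, with its log2 fold change, F. nucleatum over control, on the horizontal axis and the 25 lists past the camera threshold on the vertical axis, sorted by their median (black bars). Red and blue points are members called higher and lower by edgeR, and the medians run from 0.56 for the ATF4 amino acid response to −0.25 for cholesterol synthesis. Genes recalled from the published study make up the list named study genes.

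The genes that ATF4 switches on when amino acids run short, or when the integrated stress response is otherwise active, rose almost as a block. Of 30 tested members, 27 were higher and 1 lower (27 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.56 (camera adjusted p = 9.31e-84, and adjusted p = 0.0576 with an estimated correlation). With robust squeezing of the dispersions 22 members were called higher, and in the test against a 1.5-fold change 6 were. SESN2, a leucine sensor that restrains mTORC1, was at 97.5 ± 11.8 CPM against 34.4 ± 2.59 CPM, beside CHAC1, ATF3 and DDIT3. The cystine transporter SLC7A11 rose by 0.50 on the log2 scale (edgeR adjusted p = 2.19e-10). The exceptions were ATF5, which fell (−0.51), and ALDH1L2 (−0.07) and CBS (−0.04), which did not pass the test. These 3 were picked out after their values were seen.

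Genes of the unfolded protein response of the endoplasmic reticulum moved in both directions, with 10 of 25 members higher and 3 lower (11 higher and 4 lower adjusted over the list alone, median log2 fold change 0.12, camera adjusted p = 3.57e-05, and adjusted p = 0.0576 with an estimated correlation). The sensor kinase ERN1 (IRE1) and its target XBP1 rose by 0.88 and 0.59 on the log2 scale, the degradation factor HERPUD1 by 0.67 and the chaperone HSPA5 (BiP) by 0.31. The members that fell were the protein disulfide isomerases PDIA3 (−0.22), PDIA4 (−0.19) and PDIA6 (−0.20), named after their values were seen. Cytosolic and mitochondrial heat shock proteins did not rise: 0 members were higher and 6 of 21 lower (0 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0314, and adjusted p = 0.344 with an estimated correlation), among them the mitochondrial chaperonin HSPD1 (−0.32), HSP90AB1 (−0.19) and HSP90AA1 (−0.19). The camera call for heat shock proteins was lost without F. nucleatum replicate 2 (adjusted p = 0.220, 3 members lower) and without control replicate 1 (adjusted p = 0.0777, 3 lower).

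The list of p53 target genes had 9 higher and 4 lower of 24 tested members (9 higher and 6 lower adjusted over the list alone, camera adjusted p = 3.50e-05, and adjusted p = 0.0576 with an estimated correlation). GDF15, a stress-induced cytokine, was at 143 ± 24.4 CPM against 67.7 ± 0.963 CPM, and the cell cycle inhibitor CDKN1A (p21) rose by 1.16 on the log2 scale, beside SESN2. BTG2, an antiproliferative target of p53, fell by 0.89, and so did TP53INP1 (−0.68), CCNG1 (−0.22) and MDM2 (−0.16), the ubiquitin ligase that p53 induces against itself. The last 3 were named after their values were seen. SESN2 belongs to the ATF4 list as well, and whether p53 itself acted on any gene of this list was not tested. Among apoptosis regulators 8 of 30 members were higher and 4 lower (9 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0182, and adjusted p = 0.331 with an estimated correlation), with 2 lower without F. nucleatum replicate 2, 2 without control replicate 1 and 2 without control replicate 3. The pro-death BH3-only genes PMAIP1 (NOXA, 1.26) and BBC3 (PUMA, 0.68) rose together with the pro-survival genes BIRC3 (1.28) and MCL1 (0.25). Without the members that other lists hold, the camera adjusted p of the apoptosis list was 0.0848.

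Of the core autophagy genes, 7 of 36 were higher and 0 lower (7 higher and 0 lower adjusted over the list alone, median log2 fold change 0.08, camera adjusted p = 0.00996, and adjusted p = 0.110 with an estimated correlation). MAP1LC3B, the LC3 protein of the autophagosome membrane, was at 68.5 ± 7.05 CPM against 42.9 ± 2.35 CPM. The cargo receptors SQSTM1 (p62) and CALCOCO2 (NDP52) rose by 0.50 and 0.45 on the log2 scale. The number of members called higher was 4 without F. nucleatum replicate 2 and 4 without control replicate 3, and 2 were lower without F. nucleatum replicate 1. In the lysosome list, 7 of 28 members were higher and 1 lower (8 higher and 2 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0591), except without F. nucleatum replicate 1 (adjusted p = 0.0357) and by fry (adjusted p = 0.0104). The number of its members called higher was 4 without F. nucleatum replicate 3, 4 without control replicate 1 and 4 without control replicate 3. The acid glucosidase GAA (0.74) and the lysosomal transcription factor TFE3 (0.34) rose.

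The published study of this series is recalled, without a source to check it against, to centre on 5 genes, so their values are no independent evidence of a direction. ULK1, the kinase that starts autophagy, was at 60.5, 81.3 and 90.9 CPM in the F. nucleatum libraries against 54.6 ± 0.923 CPM in control cells (log2 fold change 0.51, SE 0.078, edgeR adjusted p = 2.90e-06). With robust squeezing of the dispersions its edgeR adjusted p was 0.114. BIRC3 (cIAP2), an inhibitor of apoptosis induced by NF-kB, was at 14.3 ± 1.66 CPM against 5.90 ± 1.41 CPM (log2 fold change 1.28, SE 0.14, edgeR adjusted p = 2.23e-09). ATG7, the enzyme that activates LC3 conjugation, was at 39.6 ± 1.14 CPM against 37 ± 2.14 CPM and did not pass (edgeR adjusted p = 0.472). Neither did MYD88, the adaptor of Toll-like receptors, at 39.3 ± 7.21 CPM against 44.7 ± 0.961 CPM (edgeR adjusted p = 0.134), nor TLR4, the receptor of lipopolysaccharide, at 7.71 ± 1.33 CPM against 7.98 ± 0.678 CPM (edgeR adjusted p = 0.866). The log2 fold change of TLR4, −0.06, changed sign without F. nucleatum replicate 2 (0.084) and lay just above 0 without control replicate 1. As a list, these genes had 2 higher and 0 lower (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0110, and adjusted p = 0.227 with an estimated correlation), and the call was lost without F. nucleatum replicate 3 (camera adjusted p = 0.0975, 1 lower).

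Of the NF-kB target genes, 12 of 25 were higher and 0 lower (16 higher and 0 lower adjusted over the list alone, median log2 fold change 0.24, camera adjusted p = 1.41e-07, and adjusted p = 0.0733 with an estimated correlation), with 7 higher without F. nucleatum replicate 3. Beside BIRC3, the adhesion molecule ICAM1 was at 6.35 ± 0.815 CPM against 2.98 ± 0.907 CPM, and cyclooxygenase-2 (PTGS2) at 29 ± 4.76 CPM against 18.5 ± 1.31 CPM. Among chemokines and cytokines 6 of 16 were higher and 0 lower (6 higher and 0 lower adjusted over the list alone, camera adjusted p = 1.19e-04, and adjusted p = 0.0690 with an estimated correlation), and 3 were higher without F. nucleatum replicate 3 and 3 without control replicate 2. The neutrophil chemokine IL8 (CXCL8 in current nomenclature) was at 8.91 ± 0.547 CPM against 4.33 ± 0.338 CPM, and TGFB2 rose by 0.54 on the log2 scale. CXCL1, CXCL2 and CXCL3 are near-identical copies, so their separate counts are uncertain. Of 8 tested genes of mucosal antimicrobial defence, 4 rose and 2 fell (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 8.86e-05, and adjusted p = 0.0658 with an estimated correlation). The siderophore-binding LCN2 was at 116 ± 10.7 CPM against 63.3 ± 0.0726 CPM, S100P at 165 ± 14.9 CPM against 99.6 ± 5.73 CPM and the elastase inhibitor PI3 at 4.75 ± 0.230 CPM against 1.75 ± 0.775 CPM, whereas the superoxide-producing oxidase NOX1 was lower, at 28.1 ± 1.46 CPM against 45.2 ± 1.61 CPM.

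Interferon-stimulated genes rose with 19 of 29 members higher and 0 lower (24 higher and 0 lower adjusted over the list alone, median log2 fold change 0.45, camera adjusted p = 5.90e-18, and adjusted p = 0.0517 with an estimated correlation). IFI27 was at 13 ± 2.35 CPM against 6.54 ± 0.641 CPM and the exonuclease ISG20 at 16.3 ± 1.70 CPM against 8.72 ± 0.250 CPM. OAS3, a sensor of double-stranded RNA, and the antiviral gene SAMD9 rose by 0.39 and 0.44 on the log2 scale. In the antigen presentation list 8 of 19 members were higher and 0 lower (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.01e-05, and adjusted p = 0.0576 with an estimated correlation; 1 lower without F. nucleatum replicate 1), including the class I gene HLA-E (0.33), B2M (0.29) and the peptide transporter TAP2 (0.49). Counts of single HLA genes are uncertain because the genes resemble each other closely. Of the Toll-like and Nod-like receptor genes 5 of 22 were higher and 0 lower (5 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.110 with an estimated correlation), and the camera call was lost without F. nucleatum replicate 3 (adjusted p = 0.0535, 1 lower). IRAK2 (0.50), CARD9 (0.32) and TAB2 (0.22), which relay signals from these receptors, rose.

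Among immediate early genes, which growth factors and stress switch on within minutes, 19 of 31 were higher and 3 lower (21 higher and 3 lower adjusted over the list alone, median log2 fold change 0.29, camera adjusted p = 4.45e-12, and adjusted p = 0.110 with an estimated correlation). EGR1 was at 55.4 ± 4.17 CPM against 32 ± 1.84 CPM, and DUSP6, a phosphatase that acts on ERK, at 99.2 ± 1.26 CPM against 75.4 ± 0.728 CPM. ATF3 rose and BTG2 fell, as given above. The hypoxia response list passed camera (camera adjusted p = 5.19e-04, and adjusted p = 0.0690 with an estimated correlation) on few members: 4 of 25 were higher and 0 lower (5 higher and 2 lower adjusted over the list alone), with 1 lower without F. nucleatum replicate 1, 1 without F. nucleatum replicate 2 and 2 with upper-quartile normalization or library totals only. VEGFA, the angiogenic growth factor, was at 329 ± 28.7 CPM against 172 ± 6.19 CPM, DDIT4 rose as above, and the glucose transporter SLC2A1 rose by 0.21 on the log2 scale. PDK1 (0.25) was the other, and its call was lost without control replicate 2 (edgeR adjusted p = 0.0808). CA9 had a log2 fold change of −0.11 and NDRG1 of −0.26, neither past the test. Both were named after their values were seen.

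NRF2 target genes, which protect against oxidants, had 10 higher and 2 lower of 24 members (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.51e-05, and adjusted p = 0.110 with an estimated correlation). The ferritin chains FTH1 (0.65) and FTL (0.25), the quinone reductase NQO1 (0.26) and SLC7A11 (0.50) rose, although ferritin genes have many processed pseudogenes and their counts are uncertain. The number of higher members was 6 without F. nucleatum replicate 2, 6 without F. nucleatum replicate 3 and 6 without control replicate 1, and that of lower members 1 without F. nucleatum replicate 3 and 1 without control replicate 1. Metallothioneins and zinc transporters did not pass as a list (camera adjusted p = 0.593). Of 7 tested members 1 was higher and 1 lower (1 higher and 1 lower adjusted over the list alone). MT1E, a member of a family of close copies, fell by 0.47 on the log2 scale. The higher member, MT2A (0.49), lost its call in several other settings, among them without F. nucleatum replicate 1 (log2 fold change 0.32, edgeR adjusted p = 0.297).

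Of 31 tested members of the mitosis list 23 were lower and 0 higher (0 higher and 26 lower adjusted over the list alone), with a median log2 fold change of −0.24 and a range from −0.46 to 0.04 (camera adjusted p = 2.49e-17, and adjusted p = 0.0517 with an estimated correlation). The checkpoint kinase TTK was at 45.9 ± 2.70 CPM against 63.2 ± 5.49 CPM, the kinesin CENPE at 78 ± 9.89 CPM against 104 ± 3.12 CPM and topoisomerase TOP2A at 435 ± 19.8 CPM against 528 ± 1.81 CPM, and the spindle motor KIF11 fell by 0.37 on the log2 scale. Replication-dependent histones had 9 of 18 members lower and 0 higher (0 higher and 10 lower adjusted over the list alone, median −0.15, camera adjusted p = 2.41e-06, and adjusted p = 0.299 with an estimated correlation), with HIST1H1B at 207 ± 16 CPM against 303 ± 21.1 CPM and HIST1H3B at 142 ± 3.81 CPM against 182 ± 13.9 CPM. Histone genes are close copies of each other, and 3 were lower without F. nucleatum replicate 2 and 2 without control replicate 2, while 1 was higher without F. nucleatum replicate 1. The DNA replication list did not pass (camera adjusted p = 0.503), with 3 higher and 3 lower of 36 (4 higher and 3 lower adjusted over the list alone), and 5 lower without F. nucleatum replicate 1. Its members CDC6, which loads the replicative helicase, rose (0.40) and RRM1, a ribonucleotide reductase subunit, fell (−0.31).

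Ribosome biogenesis genes did not pass as a list (camera adjusted p = 0.206), with 3 higher and 6 lower of 30 (3 higher and 6 lower adjusted over the list alone), and 2 lower without F. nucleatum replicate 2 and 2 without control replicate 2. NAT10 fell (−0.27) and RRP12 rose (0.33). Cytosolic ribosomal proteins had 2 higher and 3 lower of 64 (2 higher and 2 lower adjusted over the list alone), and did not pass either (camera adjusted p = 0.657). Without F. nucleatum replicate 1 these counts were 7 higher and 10 lower, and 1 was lower without F. nucleatum replicate 2. With other scalings, 6 were lower with upper-quartile normalization and 7 with library totals only. RPL15 (0.19) and RPS27A (−0.35) had the smallest p-values of that list, whose genes have many processed pseudogenes.

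Of 24 tested members of the cholesterol list, 15 were lower and 0 higher (0 higher and 18 lower adjusted over the list alone, median log2 fold change −0.25, camera adjusted p = 3.16e-13, and adjusted p = 0.110 with an estimated correlation), with 9 lower without control replicate 2. EBP was at 43.5 ± 1.23 CPM against 57.8 ± 2.61 CPM, and LSS (−0.37) and DHCR7 (−0.33), enzymes of the later steps, fell too. INSIG1, which retains the sterol regulators in the endoplasmic reticulum, was at 30.7 ± 8.33 CPM against 55.6 ± 4.55 CPM, with an edgeR adjusted p of 1.35e-09 that became 0.0664 with robust squeezing. The list of fatty acid synthesis and lipid storage had 4 higher and 7 lower of 20 members (5 higher and 9 lower adjusted over the list alone, median −0.19, camera adjusted p = 5.40e-04, and adjusted p = 0.105 with an estimated correlation), with 2 higher without F. nucleatum replicate 3. The desaturase SCD was at 305 ± 16.7 CPM against 515 ± 5.68 CPM, fatty acid synthase FASN at 493 ± 31.6 CPM against 624 ± 29.6 CPM, and ACACA (−0.28) and ACSL1 (−0.42) fell. The 4 higher members, named after their values were seen, were the lipid droplet genes PLIN2 (0.64) and PLIN3 (0.26), the acyltransferase AGPAT2 (0.28) and the carnitine palmitoyltransferase CPT1A (0.19).

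Glycolytic genes had 8 lower and 3 higher of 19 members (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00161, and adjusted p = 0.331 with an estimated correlation), with 1 higher without F. nucleatum replicate 3 and 1 without control replicate 1. GPI was at 383 ± 7.54 CPM against 482 ± 29.2 CPM, LDHA fell by 0.32 and LDHB by 0.28 on the log2 scale, while the phosphofructokinase PFKP rose (0.28). Nuclear genes of oxidative phosphorylation had 4 of 38 lower and 0 higher (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0358, and adjusted p = 0.370 with an estimated correlation). Their camera call was lost without F. nucleatum replicate 2 (adjusted p = 0.176) and without control replicate 2 (adjusted p = 0.145). The called members were ATP5L (−0.26), NDUFA4 (−0.21), NDUFB3 (−0.25) and SDHA (−0.16), of which edgeR called 1 without F. nucleatum replicate 2, 0 without control replicate 1 and 0 without control replicate 2. NDUFB3 had a log2 fold change of −0.12 without F. nucleatum replicate 2 (edgeR adjusted p = 0.524). Mitochondrially encoded transcripts had 6 of 15 higher and 0 lower (6 higher and 1 lower adjusted over the list alone, median log2 fold change 0.11, camera adjusted p = 2.09e-05, and adjusted p = 0.331 with an estimated correlation). Without F. nucleatum replicate 1 the counts were 6 higher and 3 lower and the median fell to 0.0064, so the shift of the list as a whole rests largely on that library, although camera with the preset correlation still passed (adjusted p = 0.00725). In that list 1 was lower without control replicate 3. Its lowest log2 fold change, −0.80, was that of a mitochondrial ribosomal RNA. The other mitochondrial ribosomal RNA fell as well, and neither passed the threshold over all genes. MT-ND1 was at 1725 ± 179 CPM against 1100 ± 7.36 CPM and MT-ND2 at 1491 ± 202 CPM against 931 ± 26.9 CPM, and MT-CYB (0.45) and MT-CO3 (0.31) rose less. Together these transcripts took 2.92%, 2.63% and 2.46% of the gene counts in F. nucleatum replicates 1 to 3 and 2.38%, 2.38% and 2.40% in control replicates 1 to 3. The 95% Wilson intervals of these shares, which cover counting error only, ran from 2.91% to 2.93%, 2.63% to 2.64% and 2.45% to 2.46% in the F. nucleatum libraries. In the control libraries they ran from 2.37% to 2.38%, 2.37% to 2.39% and 2.39% to 2.40%.

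In the goblet and mucin list 8 of 18 members were lower and 2 higher (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 2.09e-05, and adjusted p = 0.0690 with an estimated correlation), DESeq2 called 5 lower and 1 higher, and leaving out any single library but F. nucleatum replicate 3 left 1 higher. Among the lower members were REG4 and MUC2, as given above, the Fc-binding mucus protein FCGBP at 12.1 ± 1.58 CPM against 21.6 ± 1.75 CPM and ATOH1, the transcription factor that specifies secretory cells, at 0.808 ± 0.135 CPM against 2.45 ± 0.523 CPM. The surface mucins MUC4 (0.67) and MUC13 (0.24), named after their values were seen, were the higher members. Wnt/beta-catenin targets had 9 lower and 2 higher of 19 (3 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.0690 with an estimated correlation), and 5 were lower without F. nucleatum replicate 2. The number called higher was 3 without F. nucleatum replicate 1 and 1 when any other single library was left out. The intestinal stem cell marker LGR5 was at 3.50 ± 0.799 CPM against 7.71 ± 0.277 CPM, MYC at 158 ± 12.5 CPM against 194 ± 5.98 CPM and CD44 at 695 ± 21.6 CPM against 813 ± 15 CPM, while JUN rose (0.28). Enterocyte markers did not pass as a list (camera adjusted p = 0.221), with 3 higher and 2 lower of 16 (3 higher and 2 lower adjusted over the list alone), and 1 lower without control replicate 2 and 1 without control replicate 3. The keratin KRT20 rose (0.60) and the transcription factor HNF4A fell (−0.38).

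Cell junction genes did not pass as a list (camera adjusted p = 0.471), with 6 higher and 1 lower of 26 (7 higher and 2 lower adjusted over the list alone). The number called higher was 3 without F. nucleatum replicate 2, 3 when any 1 control library was left out and 3 with upper-quartile normalization or library totals only, while 2 were lower without F. nucleatum replicate 1. CLDN2 fell, as above, and CLDN1, a sealing claudin, rose by 0.45 on the log2 scale. Genes of epithelial-mesenchymal transition had 3 higher and 2 lower of 11 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.341), and 1 lower without F. nucleatum replicate 2 and 1 without control replicate 3, with S100A4 lower (−0.50). In the list of drug efflux and fluoropyrimidine metabolism 3 of 23 members were higher and 4 lower (6 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.773). Its median log2 fold change (−0.02) and mean (0.03) differed in sign. The copper and platinum importer SLC31A1 rose (0.40).

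Of 6 tested leukocyte markers 0 passed edgeR's test in either direction (0 higher and 1 lower at an unadjusted p under 0.05, 0 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.473), with CORO1A at 3.57 ± 1.04 CPM against 5.23 ± 1.06 CPM and PTPRC at 10.6 ± 0.628 CPM against 11.5 ± 0.440 CPM. Of 6 tested markers of fibroblasts and endothelial cells 0 passed (0 higher and 1 lower at an unadjusted p under 0.05, 0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.593), with TAGLN at 21.7 ± 0.781 CPM against 19.2 ± 1.58 CPM and TEK at 3.55 ± 0.607 CPM against 5.19 ± 0.398 CPM. DESeq2 and limma-voom called 0 markers in either list, but some other settings called a marker lower. Upper-quartile normalization and library totals only each called 1 leukocyte marker and 1 fibroblast or endothelial marker lower. In the leukocyte list 1 was lower without F. nucleatum replicate 3, 1 without control replicate 3 and 1 after the GC correction. In the other list 1 was lower without F. nucleatum replicate 1 and 1 after the length correction.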

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

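The GC and length corrections and the lists without shared members were chosen after seeing the data, and the other alternatives were planned. The counts of 1497 higher and 1066 lower genes stayed within 1.5 times under every other scaling, filter and test except the fold threshold of 1.5, where glmTreat left 57 higher and 17 lower. DESeq2 called 1225 and 746 of 15244 genes, and limma-voom 1486 and 1055. Upper-quartile scaling and library totals shifted the median log2 fold change by −0.03 and turned the excess of higher genes into an excess of lower ones, but changed the sign of no list median. Leaving out 1 library gave 1014 to 1734 higher and 650 to 1212 lower genes, lowest for lower genes without F. nucleatum replicate 2 (650) and control replicate 1 (688). With fewer libraries the test has less power. Both counts were nevertheless highest, and above those of all 6 libraries, without F. nucleatum replicate 1. On the second principal component (19.2% of the variance) the F. nucleatum libraries ran from 28.5 (replicate 1) to −27.2 (replicate 3). Control libraries ran from −7.46 to 0.137 on it. Of 118 named genes past the threshold, 27 kept their call in all 19 settings and 104 in all but the fold threshold. 12 lost it when some library was left out.

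The numbers that the labels give the replicates do not pair the libraries: deviations of same-numbered libraries correlated at 0.00328, −0.0122 and −0.0296 across genes. No library correlated best with the library of its own number in the other group. With the replicate block 1417 genes were higher and 1000 lower, and 25 lists passed. Of the named genes, the block ended only the call of MT2A (edgeR adjusted p = 0.0527).

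The 25 list calls are the least stable result: 0 held with an estimated correlation, where 16 lists had an unadjusted p under 0.05, and fry put 20 lists past the threshold, of which lysosome was not among the 25. RLE size factors, a filter at 1 CPM and the GC and length corrections left 25 lists past it. Without members of other lists 23 passed, with 1 call lost (apoptosis regulators) and 1 list left too small to test. Leaving out 1 library gave 23 to 26, where the 26 without F. nucleatum replicate 1 include lysosome. The direction of 4 lists that were not past the threshold changed when a library or shared members were left out. Camera adjusted p-values without 1 library ranged from 0.176 to 0.551 for cytosolic ribosomal proteins, 0.0719 to 0.943 for DNA replication, 0.572 to 0.980 for drug efflux and fluoropyrimidine metabolism and 0.322 to 0.961 for markers of fibroblasts and endothelial cells. Without members of other lists they were 0.961 for DNA replication and 0.638 for drug efflux. The log2 fold change of TLR4 ranged from −0.17 to 0.084 when libraries were left out. The cause of these reversals was not tested. At this depth, the smallest simulated change was recovered for 39.5% of genes at 5 CPM or more, so changes of that size may be missed.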

Other observations

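The lists and genes in this part were chosen after seeing the data, and so were the tests of the synthetases, of the spread among mitochondrial messengers, of the pseudogene level, of RNAs without a tail at 5 CPM or more, of S phase and of the histone differences without single libraries, and the counts over other splits. The GC, length, pseudogene loss and poly(A) tests were set down before their results were seen. The adjusted p-values of the added lists are over the 7 of them with at least 5 tested members, not over the 36 lists. In a list of EGF receptors, their ligands and the receptor inhibitor ERRFI1, of 11 tested genes 6 were higher and 0 lower (camera adjusted p = 2.76e-13, and adjusted p = 0.0527 with an estimated correlation). The higher members were the ligands HBEGF (1.30), AREG (1.06), EREG (0.77) and TGFA (0.28), the receptor EGFR (0.14) and ERRFI1 (0.88), while the ligands BTC, EGF and EPGN did not pass. In the Notch pathway, which steers intestinal cells towards absorptive or secretory fates, 7 of 20 tested genes were lower and 3 higher (camera adjusted p = 0.0153, and adjusted p = 0.154 with an estimated correlation). The ligand DLL1 (−1.52) fell at a low level, 0.826 ± 0.137 CPM against 2.35 ± 0.871 CPM. The ligand DLL4 (−1.03) fell as well, while JAG1 (0.71) rose and JAG2 (−0.04) did not pass. Of 24 tested HOX genes, 8 were lower and 0 higher (camera adjusted p = 2.33e-04, and adjusted p = 0.116 with an estimated correlation). Amino acid transporters outside the ATF4 list went both ways, with 6 higher and 3 lower of 19 (camera adjusted p = 0.0153, and adjusted p = 0.158 with an estimated correlation). Their median log2 fold change was 0.0074. The glycine transporter SLC6A9 (1.54) and the neutral amino acid transporters SLC38A2 (0.73), SLC1A4 (0.63) and SLC1A5 (0.40) rose, and so did SLC43A1 (0.22) and SLC38A1 (0.15). SLC36A4 (−0.54), SLC38A5 (−0.36) and SLC6A6 (−0.34) fell.

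The first pattern weighed was the rise of the ATF4 list. A trend with GC content or transcript length is argued against as its whole cause: after each correction 27 of the 27 members called higher kept their call, and the median log2 fold change went from 0.56 to 0.55 and 0.56. A candidate explanation is an amino acid response that also reaches cytosolic tRNA charging genes outside the list. The 15 cytosolic synthetases had a mean log2 fold change of 0.16 ± 0.22 (SD) against −0.08 ± 0.12 for 17 mitochondrial ones (two-sided permutation p = 3.9e-04 with 100000 permutations over genes, which are not independent replicates). As a list the cytosolic ones had 8 higher and 0 lower, with 7 not past the threshold, and the call was lost with an estimated correlation (camera adjusted p = 1.22e-06, and adjusted p = 0.116 with an estimated correlation). Whether bacteria used up amino acids of the medium, or reached ATF4 by another route, stays open.

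The second pattern was the rise of 6 of 15 mitochondrially encoded transcripts. Both mitochondrial ribosomal RNAs of this list went the other way, the lower with log2 fold change −0.80, though neither passed the threshold over all genes. Without F. nucleatum replicate 1, 6 were higher and 3 lower and the median log2 fold change went from 0.11 to 0.0064. A larger share of mitochondrial RNA, as the whole cause, would raise the 13 messengers alike. Their log2 fold changes instead spanned 0.77, from −0.10 (MT-ND5) to 0.68 (MT-ND2), 17.1 times their median standard error. The measured share was larger with F. nucleatum (2.92%, 2.63% and 2.46% in replicates 1 to 3 against 2.38%, 2.38% and 2.40% in control). A larger share as part of the cause therefore stays open. Reads counted on 12 nuclear pseudogenes of MT-ND1 and MT-ND2 are argued against as the source: these pseudogenes held 15.4 ± 0.537 CPM in control cells, 1.30% of the 1184 CPM that both genes gained. Their own change decides nothing (a loss of −0.843% of that gain, which is a rise), because so low a level fixes its outcome. Reads that align equally well to a mitochondrial gene and to a pseudogene were not counted on either, so a shift of such reads stays open. A difference in the processing or stability of single mitochondrial transcripts in exposed cells stays open as an untested hypothesis, and the list call was lost with an estimated correlation (adjusted p = 0.331).

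The third pattern was the fall of replication-dependent histones, most of whose messengers lack a poly(A) tail. Here every listed histone messenger is treated as lacking one. Weaker capture of RNA without a tail would lower other RNAs without a tail as much. For 20 of them the median log2 fold change lay above that of the histones by 0.20 (bootstrap SE 0.058), but this was not past 2 standard errors without F. nucleatum replicate 1 (0.15, bootstrap SE 0.086), and some of these RNAs have few reads. For the 14 with at least 5 CPM, a cut added after seeing the data, the difference was 0.21 (bootstrap SE 0.053). It kept its direction and stayed past 2 standard errors without each library. Those standard errors ignore the correlation between genes, so the test cannot decide and weaker capture stays open. Fewer cells in S phase would lower the DNA replication list as well, and its median lay above the histones by 0.12 (bootstrap SE 0.058). That difference was 0.069 without F. nucleatum replicate 1, 0.080 without F. nucleatum replicate 2 and 0.085 without control replicate 2, all within 2 standard errors, and 0.21 without F. nucleatum replicate 3, so fewer cells in S phase stay open. These standard errors resample genes as if independent, although the estimated correlation between the histones was 0.585. Reads shared between histone copies, and a change in the cell cycle after S phase alongside the lower mitotic genes, stay open and were not tested.

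Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 1497 higher and 1066 lower genes, and in 1 of 10 splits, the real one, were the counts that large. The highest count of any other split was 0 in either direction by edgeR's adjusted p, with 373 to 922 genes at an unadjusted p under 0.05 against 4849 in the real split. For gene lists the real split gave 25 and the highest other 15, with F. nucleatum replicate 1 and control replicates 1 and 2 against the rest. Every other split puts exposed and control libraries together on both sides, which widens the spread within its groups. Part of the exposure difference also stays between its sides. Counts of genes and lists in those splits are thus no measure of false calls.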
